A study of Mus musculus with 6 samples.

How the data were processed

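RNA was measured in effector-memory CD8+ T cells (CD3+ CD8+ CD4- CD44+, with a further gate for the effector-memory state) sorted from spleen in an ovalbumin model of asthma, in C57BL/6 mice with an S100A4-EGFP reporter, per the labels' protocols. The 6 libraries form 2 groups of 3, S100A4-negative (EGFP-negative) and S100A4-positive (EGFP-positive), and each column of the deposited tables was matched to its sample by name. Per the submitters' processing notes, reads were handled with HISAT2 2.1.0, Cufflinks and Cuffnorm on the mouse build mm10, without saying which tool made which value. The deposited expression table gives FPKM for 55951 genes in each library. The authors' deposited comparison table gives, per the file headers, each group's mean normalized read count (a signal per gene), a log2 fold change, a p-value, an adjusted p-value and a call; no test is named for it per the file headers.

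Read numbers were recovered from the deposited FPKM and the authors' group means: in all 135018 values above 0 the result lay within 0.02 of a whole read. The length implied by FPKM and reads was within 1% of the mean transcript length of GENCODE M21 (GRCm38, the build that mm10 names) for 97.5% of 15140 genes compared. Of the gene identifiers, 55141 had an annotation in M21. The counting tool and its treatment of strand and of reads in overlapping genes are not stated in the labels, so overlapping genes and near copies are reported as uncertain. The libraries held 14925260 to 18660188 recovered reads. In all libraries 27324 genes were at 0, and 767 genes share a symbol with another gene and were kept apart by identifier.

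Genes with a mean FPKM of at least 1 across the 6 libraries were tested (13241; 42710 were left out). The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended prior variance, robust estimation left off and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. The count-based test planned for a table of raw counts was not run, as the tables hold FPKM. Gene lists, 34 in number, were written before the data were examined and tested with camera at a preset correlation of 0.01, with adjustment over the lists. Lists needed at least 3 tested members. Exact permutation tests, two-sided, were used for single values. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and statmod 1.5.0. The 34 lists cover the gate, S100 and annexin genes, T cell function, signalling, stress, interferon, apoptosis, cell cycle and metabolism, and markers of other blood cells, and the report gives the result of each; 6 further lists were written after the first results were seen, 4 of them with genes already seen to rise, and their results are in the closing section.

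The genes named follow a rule written before the data were examined. They are S100a4 and the gate genes; per direction the 10 called genes with the largest change whose groups do not overlap, with a mean FPKM of at least 5 in the higher group, leaving out predicted genes, pseudogenes and receptor or antibody gene segments; and per list up to 4 called members with the largest change, or up to 2 with the smallest p where none passed. Other list members named in the text were chosen after their values were seen. Some genes that the rule selects are not reported here by name, and they stay in the counts and tests of their lists.

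The steps were tested on simulated data with the 13241 genes and a dispersion of 0.0165, a spread between replicates taken from these libraries. Of genes changed 1.5-fold, 2-fold and 4-fold, 20.9%, 71.6% and 95.5% were called, with 11 false calls. Smaller changes can thus be missed at this depth and number of libraries. The simulation changed only 67, 67 and 66 genes at these folds and gave all genes the same dispersion. In the real comparison 8253 genes were called, so the recovery rates need not hold for it. A moved list was called (camera adjusted p = 3.65e-24) and 0 of 20 unmoved lists were. The simulated genes were drawn independently, so this does not check camera for lists whose genes move together. The alternatives tried were another pseudocount, no filter and a filter of 5, median-of-ratios rescaling, quantile normalization, limma without trend, array weights, the replicate number as a block, leaving out each library, treat, camera with an estimated correlation and fry. Limma voom on the recovered reads, with library totals or the authors' size factors, was added after seeing the data.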

Results

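Gene expression was measured by sequencing of polyadenylated RNA in effector-memory CD8+ T cells sorted from the spleens of mice with asthma induced by ovalbumin. The mice carried a reporter in which EGFP marks cells that express S100A4, a small calcium-binding protein. Cells were gated as CD3+ CD8+ CD4- CD44+ effector-memory cells and divided into EGFP-negative and EGFP-positive cells, called S100A4-negative and S100A4-positive here. Each group had 3 libraries, and 14925260 to 18660188 reads per library could be recovered from the deposited values. The labels give 3 samples per population without saying whether they came from separate animals, so the p-values measure the spread between these samples only. Levels are FPKM as deposited, given as mean ± SD with n = 3 per group, and fold changes are S100A4-positive minus S100A4-negative on the log2(FPKM + 1) scale, which understates the change of low genes.

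S100a4, the gene the reporter follows, was read at very low levels in every library. Its FPKM in the S100A4-negative libraries was listed at 0, 0.405 and 0.129, from 0, 3 and 1 recovered reads. In the S100A4-positive libraries it was 1.27, 4.02 and 1.52, from 9, 25 and 11 reads. The difference of 1.39 (SE 0.32) passed the test across all genes (limma adjusted p = 0.00778), with each S100A4-positive library above each S100A4-negative one. The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. S100a4 (ENSMUSG00000001020) lies on chromosome 3, 90603771 to 90606045 of the mouse genome build GRCm38, on the + strand. In the annotation used here, 51.7% of its exon bases also belong to Gm42674, a gene on the same strand annotated from 90601904 to 90605885, which was listed at 0 in every library. A low or 0 value of a gene with shared exons cannot be read as its level of expression. Jund, an immediate-early gene, was listed at 0 in every library.

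**Figure D1:**
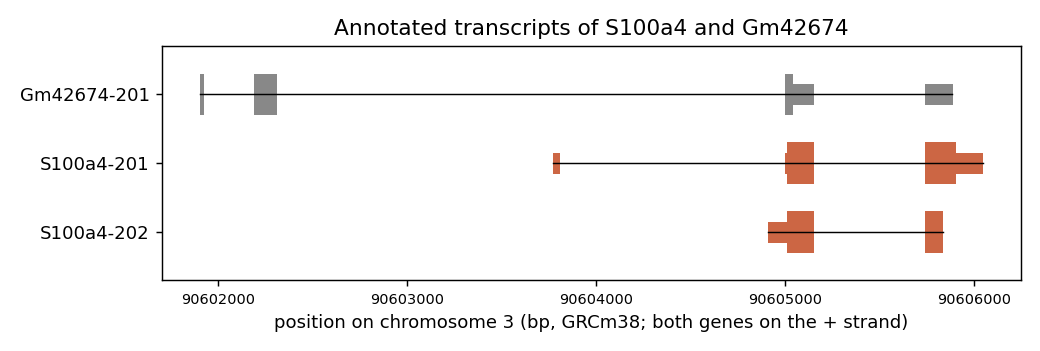
Map of the annotated transcripts of S100a4 and Gm42674 on chromosome 3 (position in bp, GRCm38), with thin boxes for untranslated and thick boxes for coding parts of exons and lines for introns. The exons of Gm42674 from 90604997 to 90605152 and from 90605740 to 90605885 overlap those of S100a4, which make up 51.7% of its exon bases.

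The comparison asked how S100A4-positive effector-memory CD8+ T cells differ from S100A4-negative ones in gene expression. Genes of monocytes and macrophages were the clearest group higher in S100A4-positive libraries: all 19 measured markers rose (camera adjusted p = 1.05e-15; 0.714 with an estimated correlation). Among them was Csf1r, the receptor for macrophage colony-stimulating factor, which rose from 22.6 ± 9.88 to 1039.9 ± 204 FPKM. The lists of T cell receptor signalling genes and of naive and central-memory genes were lower with camera's preset correlation (adjusted p = 0.00153 and 0.00945; both 0.714 with an estimated correlation). Lck, the kinase that starts T cell receptor signalling, fell from 332 ± 31.2 to 46.5 ± 11.5 FPKM, and Cd3e from 146 ± 19.1 to 23.5 ± 6.20. In S100A4-positive libraries 7 of 8 plasma cell and 11 of 13 neutrophil markers fell and 1 of each rose, and neither list was called (camera adjusted p = 0.142 and 0.0906). Immunoglobulin genes took 6.60% ± 2.20 of reads in S100A4-negative and 0.764% ± 0.448 in S100A4-positive libraries (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible).

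Of 13241 genes with a mean FPKM of at least 1, limma called 8253 at an adjusted p under 0.05, 2512 higher and 5741 lower in S100A4-positive libraries, and 8869 had an unadjusted p under 0.05. The fold change was at least 2-fold on the log2 scale used for 3818 of the called genes. In 9264 genes, 70.0% of those tested, all 3 libraries of a group lay above all 3 of the other, where chance gives 10%. The median log2 fold change of all tested genes was -0.36, and the direction of the calls depended on the scaling: 30.4% were higher with FPKM as deposited, 53.3% after median-of-ratios rescaling, which shifted the median by 0.36, and 42.0% after quantile normalization, which shifted it by 0.21. The median of each gene list is therefore also given as a relative value, which is the list's median minus that of all tested genes. In the authors' deposited table, 5420 genes were called, 3317 higher and 2103 lower, and 4461 of these were among the genes tested here. The calls shared 4264 genes, all in the same direction. These were 51.7% of the calls made here and 95.6% of the 4461 authors' calls among the genes tested here. Across 13226 genes, which are not independent replicates, the log2 fold changes had a Spearman correlation of 0.989 with those in the authors' deposited table.

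Among the sort gate genes, the T cell receptor chains Cd3d, Cd3e and Cd3g and both chains of the CD8 coreceptor fell. Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494) went from 141 ± 46.6 to 14.9 ± 5.06 FPKM, a log2 fold change of -3.15 (SE 0.30, limma adjusted p = 1.71e-04), and Cd8a from 137 ± 51.1 to 22.6 ± 9.17. The log2 fold changes of Cd3d, Cd3e and Cd3g were -2.66, -2.61 and -2.40. Cd44, which encodes the adhesion receptor used to gate memory cells, rose by 1.72 (SE 0.22, limma adjusted p = 5.70e-04) from 166 ± 38.2 to 548 ± 126 FPKM. Cd4, whose protein the gate excluded, was at 172 ± 145 and 53.8 ± 12.1 FPKM, and its difference did not pass (limma adjusted p = 0.0576), though it did with array weights and without S100A4-negative replicate 1 (0.0485 and 0.0145). The log2 fold change of Cd4 was -1.35, or -0.70 without S100A4-negative replicate 2. Over the gate list, 1 gene rose, 6 fell and 1 did not pass, and 7 fell when adjusted over the list alone; the list had a median of -2.47, relative -2.12, and was not called (camera adjusted p = 0.0944).

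**Figure D2:**
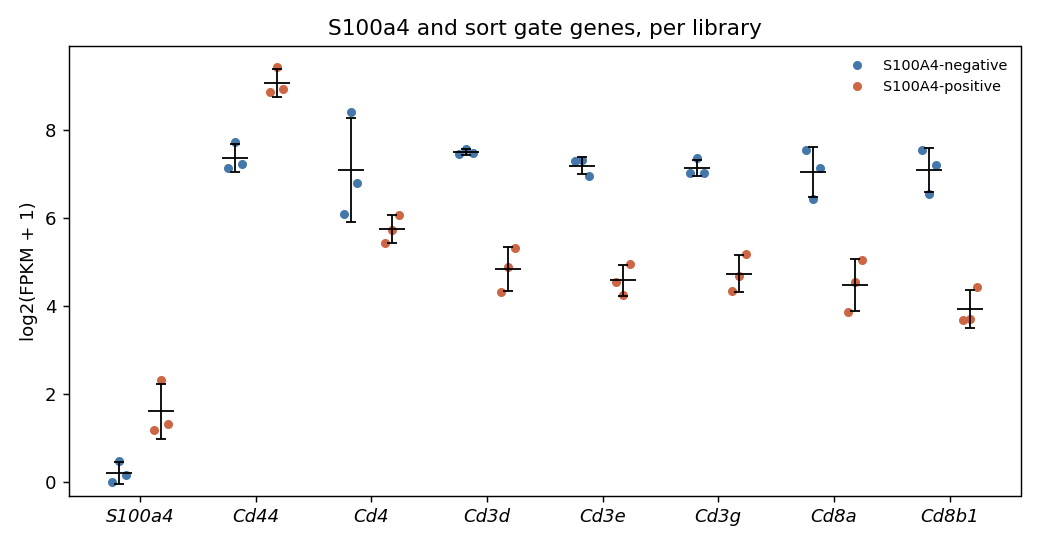
S100a4 and 7 of the sort gate genes in each library, as log2(FPKM + 1); points are libraries, and bars are the mean and SD of 3 libraries per group. The 3 S100A4-positive libraries lie below all S100A4-negative ones for Cd3d, Cd3e, Cd3g, Cd8a and Cd8b1 and above them for Cd44 and S100a4. For Cd4 they also lie below, but narrowly (66.6 FPKM at the highest against 67.2 at the lowest), and the difference did not pass.

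The monocyte and macrophage markers had a median log2 fold change of 3.41, or 3.77 relative to all tested genes (camera adjusted p = 1.05e-15; adjusted p = 0.714 with an estimated correlation). Csf1r rose by 5.52 (SE 0.29), and Cd68, a lysosomal glycoprotein of macrophages, by 4.23 from 31.0 ± 5.59 to 593 ± 76.6 FPKM. Lyz2, which encodes lysozyme, rose from 311 ± 60.9 to 3039 ± 169 FPKM, and Hmox1, the haem-degrading oxygenase, from 83.5 ± 10.1 to 1280.2 ± 161. Fcer1g and Tyrobp, signalling adaptors of myeloid and natural killer cells, rose by 3.66 and 3.31. In the same libraries the T cell receptor signalling list, described further on, had a median of -2.40.

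Of 14 dendritic cell markers, 8 rose, 0 fell and 6 did not pass, and 7 rose when adjusted over the list alone; the median was 1.38, relative 1.74 (camera adjusted p = 0.00141; adjusted p = 0.714 with an estimated correlation, and 0.0532 with fry). Without S100A4-negative replicate 1 the median was 0.89. Itgax, the integrin CD11c, rose from 43.8 ± 7.64 to 343 ± 55.6 FPKM and Flt3, a cytokine receptor of dendritic cell precursors, from 2.68 ± 2.25 to 21.8 ± 12.1. Cd209a rose by 2.06. Clec9a and Xcr1, markers of cross-presenting dendritic cells, rose by 2.04 and 1.54, but both lost their call in fits without a library. For Clec9a these were the fits without replicate 1 or 2 of the S100A4-negative or 2 or 3 of the S100A4-positive libraries (limma adjusted p of up to 0.0720), and for Xcr1 all but the one without S100A4-positive replicate 1 (up to 0.104). Chemokines moved with these markers: 6 of 9 rose, 1 fell and 2 did not pass, with a median of 2.94, relative 3.29 (camera adjusted p = 0.00724; adjusted p = 0.714 with an estimated correlation). Cxcl16 rose by 4.99, Ccl22 by 3.97, Ccl9 by 3.33 and Ccl4 by 3.16, whereas Xcl1, a chemokine made by activated T and natural killer cells, fell by 1.92. Ccl4 lost its call without S100A4-positive replicate 2 (limma adjusted p = 0.0528).

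The 10 largest rises among genes whose groups did not overlap included the peptidase gene Ace (ENSMUSG00000020681, chromosome 11, 105967945 to 105989964), which went from 0.934 ± 0.718 to 386 ± 91.4 FPKM, a log2 fold change of 7.69 (SE 0.29, limma adjusted p = 8.72e-06). The authors' deposited table gives it a log2 fold change of 9.05. Mmp14, a membrane-bound matrix metalloproteinase (chromosome 14, 54431612 to 54445364), rose by 6.38, the C-type lectin genes Clec4a1 and Clec4a3 by 6.23 and 6.02, and the adhesion receptor gene Adgre4 by 6.09. Fam20c, Ear2, Lrp1, Spic and Cd300e rose by 5.81, 5.72, 5.66, 5.65 and 5.57; Spic, a transcription factor of splenic red pulp macrophages, was at 283 ± 85.6 FPKM in S100A4-positive libraries. Clec4a1, Clec4a3 and Ear2 belong to families of similar genes, so reads could be divided among their members. The 10 largest falls were those of Jchain, Sidt1, Derl3, Cd8b1, Tdrp, Ctsw, Bicdl1, Nsg2, Nkg7 and Lef1. Jchain, the joining chain of secreted antibodies (chromosome 5, 88519809 to 88527891), fell by 3.47 (SE 0.57, limma adjusted p = 0.00177) from 1632 ± 688 to 167 ± 138 FPKM. The log2 fold changes of Sidt1, Tdrp, Bicdl1 and Nsg2 were -3.22, -3.05, -2.97 and -2.94.

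T cell receptor signalling genes had a median of -2.40, or -2.04 relative to all genes, with 16 of 19 lower, 2 higher and 1 not passing (camera adjusted p = 0.00153; adjusted p = 0.714 with an estimated correlation). Prkcq, Lck and Cd3d had log2 fold changes of -2.88, -2.83 and -2.66. The genes that rose were Lcp2 and Ptpn6, which encode an adaptor and a phosphatase that myeloid cells also use. Naive and central-memory genes followed, with 16 of 20 lower, 2 higher and 2 not passing and a median of -1.56, relative -1.20 (camera adjusted p = 0.00945; adjusted p = 0.714 with an estimated correlation). Lef1, a transcription factor of naive T cells, fell from 46.4 ± 26.1 to 4.76 ± 0.0941 FPKM, Cd28 from 61.6 ± 11.4 to 8.06 ± 1.29 and Cd27 from 139 ± 13.2 to 20.2 ± 7.27. In these same libraries the macrophage markers were higher, with a list mean of 7.97 ± 0.13 log2 units (SD, n = 3) against 4.52 ± 0.34 in S100A4-negative libraries.

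**Figure D3:**
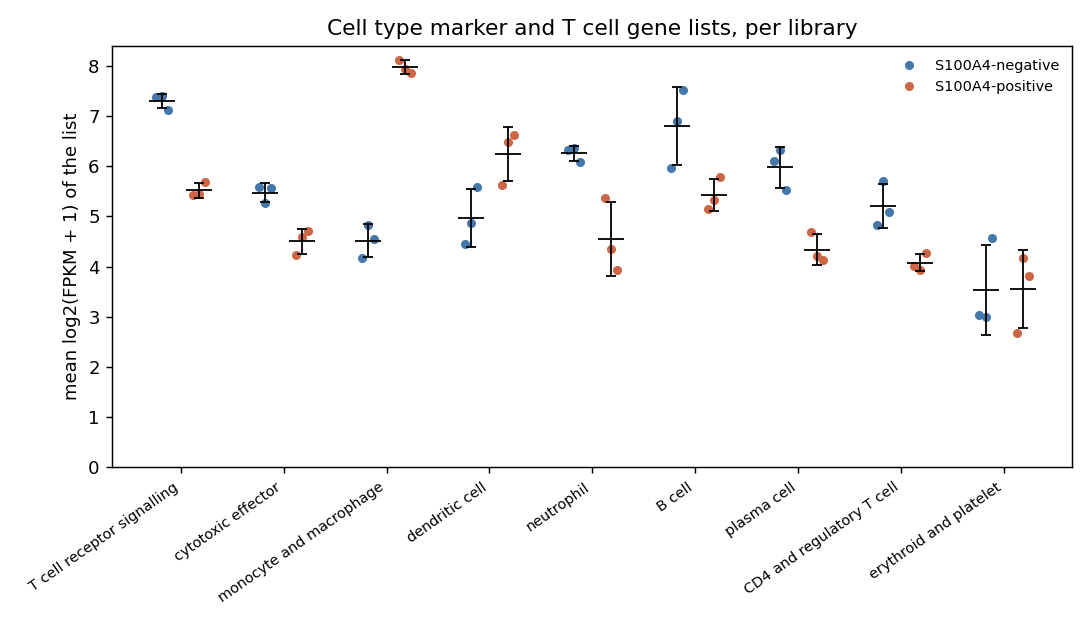
Mean log2(FPKM + 1) over the tested members of 9 gene lists in each library; points are libraries, and bars are the mean and SD of 3 libraries per group. The mean of the monocyte and macrophage list was 4.52 ± 0.34 in S100A4-negative and 7.97 ± 0.13 in S100A4-positive libraries, and that of the T cell receptor signalling list was 7.30 ± 0.15 and 5.52 ± 0.15.

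Of 18 cytotoxic effector genes, 12 fell, 4 rose and 2 did not pass, and the list was not called (median -1.47, relative -1.11, camera adjusted p = 0.362), but it was called lower with voom and the authors' size factors (0.0489) and with fry (0.0107). Ctsw and Nkg7, granule genes of cytotoxic lymphocytes, fell by 3.02 and 2.93, and the granzyme genes Gzma and Gzmk by 2.60 and 2.62; Gzma went from 34.8 ± 6.99 to 5.51 ± 3.99 FPKM (limma adjusted p = 0.00118). The members that rose were Lamp1, Ctsc, Ctsd and Srgn, which encode lysosomal and granule proteins also made by myeloid cells. Killer-cell receptors and terminal-effector markers went both ways, with 5 higher, 8 lower and 2 not passing of 15 (median -0.65, relative -0.29, mean -0.00034, camera adjusted p = 0.609). Cd244a and Cx3cr1 rose by 3.10 and 3.09, and Klrc1 and Klrc2 fell by 2.50 and 2.24. Effector transcription factors were also divided, with 5 higher, 5 lower and 2 not passing of 12. Adjusted over the list alone, 6 were lower. The list was not called (median -0.26, relative 0.10, camera adjusted p = 0.522). Without S100A4-negative replicate 2 or S100A4-positive replicate 1 its median was -0.059 and -0.15. Zeb2 and Id2 rose by 3.51 and 1.95, while Eomes and Tbx21, T-box factors of cytotoxic lymphocytes, fell by 2.89 and 2.41. Macrophage markers rose in the same libraries, as given above.

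Inhibitory receptors and exhaustion genes had 11 of 19 members lower, 4 higher and 4 not passing (median -1.21, relative -0.86, camera adjusted p = 0.609). Ctla4 and Tigit fell by 2.44 and 2.24, whereas Havcr2 and Cd244a, which myeloid cells also express, rose by 3.51 and 3.10. Pdcd1, which encodes PD-1, fell by 1.84. Of 13 cytokine genes, 3 rose, 7 fell and 3 did not pass. Adjusted over the list alone, 4 rose. The list was not called (median -0.75, relative -0.39, mean 0.085, camera adjusted p = 0.771). Tnf rose by 4.56 (SE 0.77, limma adjusted p = 0.00193) and Il18 by 1.74, while Ifng, interferon gamma, fell from 6.46 ± 1.91 to 1.56 ± 1.13 FPKM and Ltb, Il4 and Il13 fell by 1.42, 1.19 and 1.37. The type 2 genes, relevant to allergic airway inflammation, had 7 of 11 lower, 1 higher and 3 not passing (median -0.76, relative -0.40, camera adjusted p = 0.717). Gata3, the transcription factor of type 2 T cells, fell from 52.8 ± 15.4 to 11.6 ± 2.49 FPKM, and the member that rose was Pparg, a nuclear receptor also active in macrophages, by 5.39. Macrophage markers, with a median of 3.41, rose beside these lists.

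The list of S100 proteins, annexins and effector-memory cytoskeletal genes was higher, with 11 of 22 members higher, 5 lower and 6 not passing and a median of 0.50, relative 0.86 (camera adjusted p = 0.00181; adjusted p = 0.714 with an estimated correlation). Lgals3, Anxa4 and Anxa5 rose by 3.91, 3.49 and 2.87, and S100a9, a neutrophil protein, fell by 2.43. Integrins and adhesion molecules had 8 higher, 6 lower and 6 not passing of 20 (median 0.037, relative 0.39, camera adjusted p = 0.0798), and the list was called higher with a filter of 5 (0.0462). Its median turned negative without replicate 1 or 3 of the S100A4-negative or replicate 1 of the S100A4-positive libraries (-0.056, -0.030 and -0.019), and ranged up to 0.094 without S100A4-negative replicate 2. Itga5 and Icam1 rose by 5.05 and 2.04 and Cd226 fell by 2.48. Chemokine receptors had 3 higher, 6 lower and 7 not passing of 16 (median -0.84, relative -0.48, camera adjusted p = 0.771). Their median was -0.46 and -0.49 without S100A4-negative replicates 2 and 3 in turn. Cx3cr1 was higher, and Cxcr3 and Cxcr5 were lower by 2.37 and 1.53. Tissue-resident memory genes had 4 higher, 6 lower and 3 not passing of 13 (median -0.45, relative -0.10, camera adjusted p = 0.717), and their median was -0.25 without S100A4-positive replicate 3. Litaf rose by 2.40 and Cd69 and Zfp683 fell by 1.53 and 1.53. Beside these 4 lists, the macrophage list had a median of 3.41.

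Markers of other cell types that the gate excludes were present. Of 14 B cell markers, 11 fell, 0 rose and 3 did not pass (median -1.30, relative -0.94, camera adjusted p = 0.0722). Ighm went from 8931 ± 2468 to 1187 ± 121 FPKM and Cd79a from 247 ± 108 to 79.4 ± 23.2. Of 8 plasma cell markers, 7 fell and 1 rose (median -1.74, relative -1.38, camera adjusted p = 0.142), among them Derl3 and Tnfrsf17 with log2 fold changes of -3.20 and -2.04; Mzb1, at -1.89, shares 57.2% of its exon bases with another gene. Of 13 neutrophil markers, 11 fell, 1 rose and 1 did not pass (median -2.08, relative -1.72, camera adjusted p = 0.0906), with S100a9 going from 1349 ± 271 to 286 ± 201 FPKM and Ngp, Ltf and Camp falling by 2.81, 2.69 and 2.69. These 3 lists and the sort gate list were called after median-of-ratios rescaling (camera adjusted p = 0.0127, 0.0422, 0.0127 and 0.0185 for B cell, plasma cell, neutrophil and gate genes), with voom and the authors' size factors (0.00757, 0.0408, 0.0111 and 0.0112) and without a filter (0.0124, 0.0386, 0.0187 and 0.0264). Quantile normalization gave calls of the B cell, neutrophil and gate lists (camera adjusted p = 0.0277, 0.0376 and 0.0378). The B cell list was also called with voom and library totals (0.0478) and without S100A4-negative replicate 1 or S100A4-positive replicate 3 (0.00186 and 0.0467), all with camera. The neutrophil list was called with array weights (camera adjusted p = 0.0311) and without S100A4-negative replicate 3 or S100A4-positive replicate 1 (0.0415 and 0.00813). CD4 and regulatory T cell markers had 7 lower and 3 not passing of 10, and 8 lower and 1 higher when adjusted over the list alone (median -1.26, relative -0.91, camera adjusted p = 0.152), but the list was called without a filter (0.0351). Tnfrsf18 and Cd40lg fell by 1.65 and 1.79, and Cd40lg lost its call with voom and the authors' size factors (limma adjusted p = 0.0682).

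Eosinophil, basophil and mast cell markers had 3 higher, 6 lower and 1 not passing of 10 (median -1.45, relative -1.10, camera adjusted p = 0.774), with a median of -0.88 without S100A4-negative replicate 3. Ear2 rose, and Gata2 and Prg2 fell by 2.60 and 2.56, while the fall of Mcpt8 by 2.32 was lost without S100A4-negative replicate 2 or any 1 S100A4-positive library (limma adjusted p from 0.0554 to 0.0895) and, among other settings, after median-of-ratios rescaling (0.0651). Without S100A4-negative replicate 3, where Mcpt8 was at 52.0 FPKM against 4.50 and 9.72 in the other S100A4-negative libraries, its log2 fold change was -1.39. NK and innate lymphoid cell markers had 3 higher, 5 lower and 1 not passing of 9. Adjusted over the list alone, 6 were lower. The list was not called (median -0.72, relative -0.36, camera adjusted p = 0.764), and the rise was in Fcer1g, Tyrobp and Kit. Of the gamma-delta T cell markers only 3 were tested, of which 2 rose and 1 fell. Trdv4 rose by 1.51 and Blk fell by 1.24, a call lost without S100A4-negative replicate 2 (limma adjusted p = 0.0556) and after median-of-ratios rescaling (0.0733). The list was not called (median 1.30, relative 1.66, camera adjusted p = 0.324), except without a filter (0.0333). Of 8 erythroid and platelet markers, 1 fell, Itga2b with a log2 fold change of -1.79, and 7 did not pass (median 0.34, relative 0.70, camera adjusted p = 0.634). That median rests on single libraries, as it was -0.045 without S100A4-negative replicate 1 and 0.89 without S100A4-negative replicate 3.

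Cell-cycle genes were lower, with 20 of 22 members lower and 2 not passing and a median of -1.25, relative -0.89 (camera adjusted p = 0.00141; adjusted p = 0.767 with an estimated correlation). Mcm6, a subunit of the replication helicase, fell from 118 ± 5.23 to 30.2 ± 5.20 FPKM and Ccne1 from 13.4 ± 3.71 to 3.52 ± 0.854; Top2a and Rrm2 fell by 1.53 and 1.51. Interferon-response genes were higher, with 9 higher, 2 lower and 11 not passing of 22 (median 0.74, relative 1.10, camera adjusted p = 0.00189; adjusted p = 0.714 with an estimated correlation). The median was 0.42 without S100A4-negative replicate 1. Rsad2, Oasl2 and Oas2 rose by 2.18, 1.73 and 1.55, and Gbp4 fell by 1.63. Apoptosis genes were higher as a list, with 11 higher, 4 lower and 6 not passing of 21 (median 0.59, relative 0.95, camera adjusted p = 0.00153; adjusted p = 0.714 with an estimated correlation). The members that rose most were Bcl2a1d, Bcl2a1b and Mcl1, which inhibit apoptosis, by 2.73, 1.97 and 1.13, and Pmaip1, which promotes it, by 1.78; Bcl2a1b and Bcl2a1d are near copies whose reads could be divided. Immediate-early genes had 7 higher, 3 lower and 7 not passing of 17 (median 0.59, relative 0.94, camera adjusted p = 0.0319; adjusted p = 0.714 with an estimated correlation), with Atf3 and Ier3 higher by 2.33 and 2.32; this call was also lost with median-of-ratios rescaling, quantile normalization, a filter of 5 and fry (adjusted p = 0.0521, 0.111, 0.0599 and 0.0826) and without replicate 3 of either group (camera adjusted p = 0.0658 and 0.0603). Its median was 0.37, 0.39 and 0.36 without S100A4-negative replicate 2, S100A4-positive replicate 1 and S100A4-positive replicate 3. Heat-shock genes had 3 higher, 6 lower and 3 not passing of 12 (median -0.40, relative -0.039, camera adjusted p = 0.869), or a median of -0.25 without S100A4-positive replicate 1, with Hspa1a higher by 1.33 and Hsph1 and Dnaja1 lower by 1.27 and 1.06 in log2 units. In these same libraries monocyte and macrophage markers were higher (median 3.41), and medians of the T cell receptor signalling, B cell and plasma cell lists were -2.40, -1.30 and -1.74.

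Among metabolic lists, fatty acid oxidation genes were higher, with 5 higher, 3 lower and 7 not passing of 15 (median 0.092, relative 0.45, camera adjusted p = 0.0465; adjusted p = 0.738 with an estimated correlation). The largest rises in it were those of Fabp5 and Cd36, a fatty acid carrier and a fatty acid and scavenger receptor, by 3.85 and 3.23, while Hadhb, an enzyme of the pathway itself, fell by 0.66, which did not pass after median-of-ratios rescaling (limma adjusted p = 0.0683). The list's call was lost without S100A4-negative replicate 2, S100A4-positive replicate 1 or S100A4-positive replicate 3 (camera adjusted p from 0.0520 to 0.0695), and with no filter or a filter of 5 (0.0515 and 0.0599). Its median was 0.18, 0.20 and 0.057 without S100A4-negative replicate 1, S100A4-positive replicate 2 and S100A4-positive replicate 3. Mitochondrially encoded genes were lower, with 9 of 11 lower and 2 not passing (median -0.69, relative -0.33, camera adjusted p = 0.0465; adjusted p = 0.817 with an estimated correlation), and mt-Nd2 went from 1369.9 ± 48.3 to 769 ± 28.7 FPKM; the call was lost without S100A4-negative replicate 1, S100A4-positive replicate 2 or S100A4-positive replicate 3 (camera adjusted p from 0.0601 to 0.0862) and with quantile normalization (0.0552). Glycolysis genes had 8 higher, 4 lower and 4 not passing of 16. Adjusted over the list alone, 5 were lower. The list was not called (median 0.20, relative 0.56, camera adjusted p = 0.0944). It was called higher after median-of-ratios rescaling (median 0.59, camera adjusted p = 0.0267) and with voom and the authors' size factors (0.0225), with the lactate exporter gene Slc16a3 higher by 2.09 and the glucose transporter gene Slc2a3 lower by 1.23 in log2 units. Of 24 nuclear genes of oxidative phosphorylation, 2 were lower and 22 did not pass, and 0 were lower when adjusted over the list alone (median -0.020, relative 0.34, camera adjusted p = 0.503). Its median turned positive without replicate 2 or 3 of the S100A4-negative or replicate 1 of the S100A4-positive libraries (0.016, 0.041 and 0.056). It was -0.17, -0.078 and -0.11 without S100A4-negative replicate 1, S100A4-positive replicate 2 and S100A4-positive replicate 3. Ndufs3 and Ndufs7 had log2 fold changes of -0.52 and -0.53, which did not pass after median-of-ratios rescaling (limma adjusted p = 0.446 and 0.226), where the list was called higher (camera adjusted p = 0.0438). The call of Ndufs3 was also lost with quantile normalization (limma adjusted p = 0.0616). The same held without replicate 2 or 3 of the S100A4-negative or replicate 1 or 2 of the S100A4-positive libraries (limma adjusted p from 0.0559 to 0.0849). Cholesterol and fatty acid synthesis genes had 4 higher, 7 lower and 10 not passing of 21 (median -0.22, relative 0.14, camera adjusted p = 0.874). Fasn and Scd2, which encode enzymes of fatty acid synthesis, fell by 1.28 and 1.28. Beside these metabolic lists, monocyte and macrophage markers had a median of 3.41 and T cell receptor signalling genes one of -2.40.

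**Figure D4:**
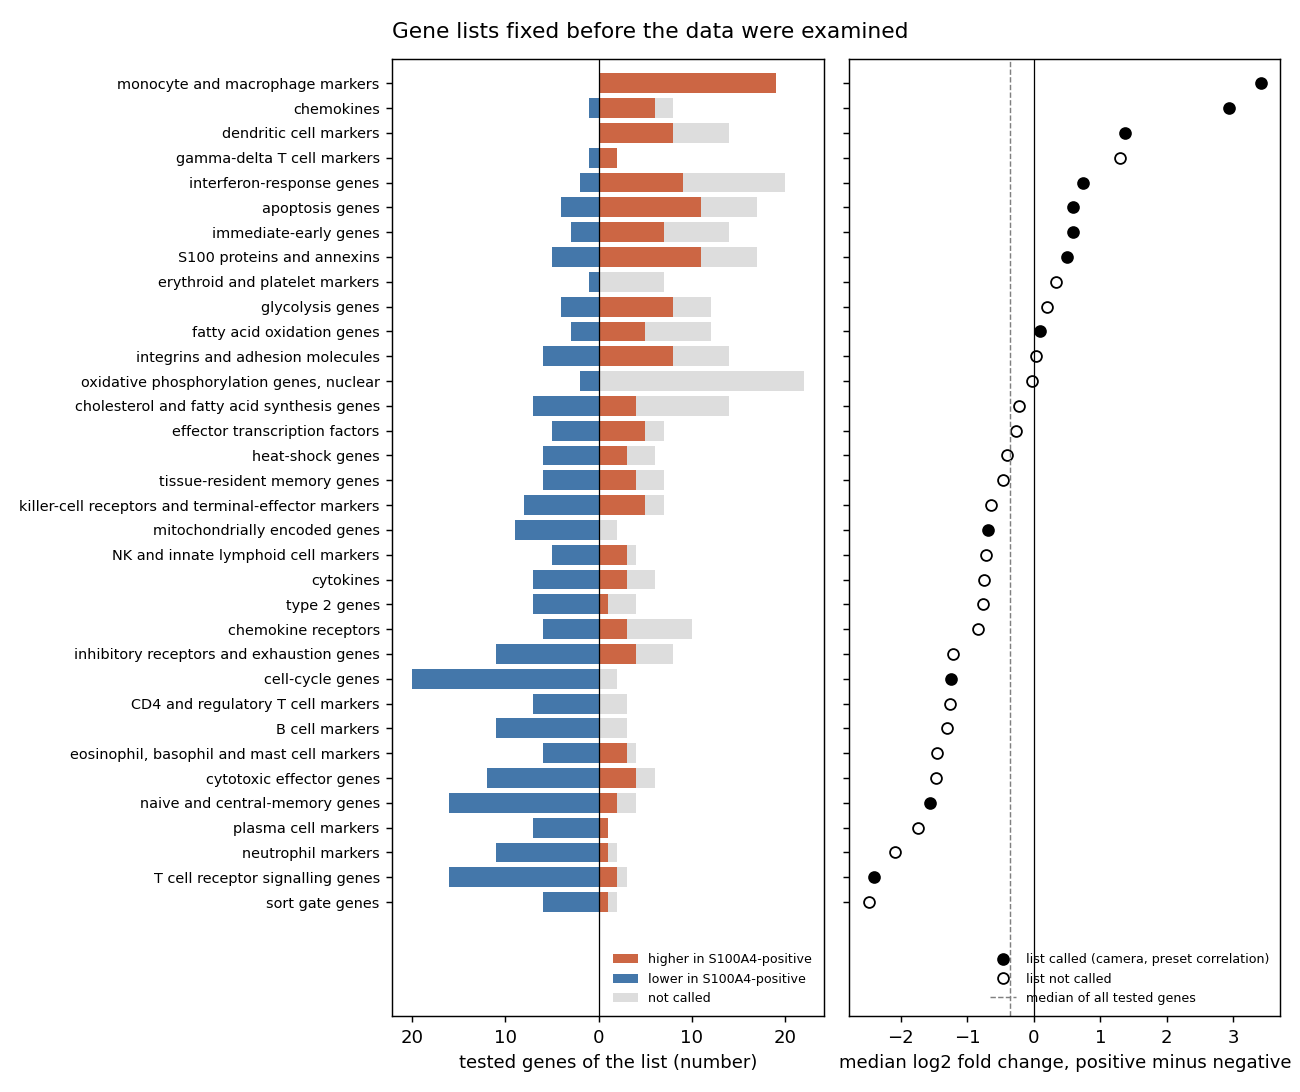
For each of 34 gene lists, the left panel gives the number of tested genes called higher, called lower or not called in S100A4-positive libraries, and the right panel the median log2 fold change, with filled points for lists called by camera with the preset correlation. The monocyte and macrophage markers had the highest median, 3.41, and the sort gate genes the lowest, -2.47; the dashed line is the median of all tested genes, -0.36.

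Of the 34 lists, 12 were called with the preset correlation and 0 with an estimated correlation, for which the lowest adjusted p was 0.714; the same 34 lists gave 21 calls with fry, which asks whether a list's genes move and does not compare them with other genes. Among lists that camera did not call, fry called the sort gate, cytotoxic and inhibitory receptor lists lower (fry adjusted p = 0.00315, 0.0107 and 0.0198). It called the integrin, glycolysis and NK lists higher (fry adjusted p = 0.00626, 0.0283 and 0.00757), the NK list in spite of its median of -0.72. Fry also called the B cell, plasma cell, neutrophil, CD4 and chemokine receptor lists lower (fry adjusted p = 0.0476, 0.00966, 0.0258, 0.0132 and 0.0117). In 26 lists the counts adjusted over the list alone equalled those over all genes, and those of the other lists are given above. In 9 lists the median, mean and test did not share a sign: killer-cell receptors, effector transcription factors, cytokines, chemokine receptors, tissue-resident memory genes, oxidative phosphorylation genes, cholesterol and fatty acid synthesis genes, eosinophil, basophil and mast cell markers, and NK and innate lymphoid cell markers. After rescaling, the median of the effector transcription factors, oxidative phosphorylation genes and cholesterol and fatty acid synthesis genes turned positive, at 0.12, 0.36 and 0.12.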

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

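The tests with voom were chosen after seeing the data; the others were planned. Over all settings that tested S100a4, it stayed higher and called, with log2 fold changes from 1.04 to 3.81 and limma adjusted p from 0.00383 to 0.0263; a mean FPKM of at least 5 leaves it out. The number of called genes ranged from 6198 with a filter of 5 to 8916 without a filter, and 6881 to 8168 without single libraries. Of the genes called both there and in another setting, 0 had the opposite direction. The genes called lower went from 5741 to 3217 after median-of-ratios rescaling and 3156 with voom and the authors' size factors. These settings shifted the median log2 fold change of all tested genes upward, by 0.36 and 0.37. Which scaling is right was not tested. Of 34 lists, 12 were called, against 19 with that voom, 0 with camera and an estimated correlation and 21 with fry (without single libraries 10 to 12); the cause was not tested. Among named genes, 2142 results were the same, 49 lost and 3 gained their call, and 0 reversed; among lists 513 were the same, 41 gained and 28 lost a call. The replicate number as a block gave 8857 calls, 8135 of them shared, and added calls of Cd4 (adjusted p = 0.0346), the B cell list (0.0112) and the neutrophil list (0.0467) and of no other named gene or list; same-numbered libraries did not all deviate together (correlations of 0.376, 0.0830 and 0.366), and pairing was not assumed.

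Lists also changed camera's direction, which is relative to other genes, with these medians, none of them called there; the cause was not tested. No filter: cholesterol and fatty acid synthesis -0.30, eosinophil, basophil and mast cell -1.10. Filter of 5: type 2 -0.60. Median-of-ratios: cytokines -0.37, chemokine receptors -0.51, tissue-resident memory -0.21, eosinophil, basophil and mast cell -1.28, NK -0.43. Quantile: cytokines -0.59, eosinophil, basophil and mast cell -1.35. Array weights: heat-shock -0.29. Voom with size factors: cytokines -0.38, chemokine receptors -0.53, tissue-resident memory -0.37, eosinophil, basophil and mast cell -2.41, NK -0.56. Without single libraries, ranges of lists that changed direction: chemokine receptors -0.85 to -0.46, cholesterol -0.28 to -0.21, eosinophil, basophil and mast cell -1.76 to -0.88, heat-shock -0.45 to -0.25. Fry tests a list against no change, and its direction differed from camera's for cytokines -0.75, chemokine receptors -0.84 (adjusted p = 0.0117), tissue-resident memory -0.45, oxidative phosphorylation -0.020, cholesterol -0.22, erythroid 0.34, whose medians are those reported; only chemokine receptors among them were called. Apart from voom on the recovered reads, tests for raw counts were not run, as the tables hold FPKM. At this depth S100a4 rests on 4 and 45 reads.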

Other observations

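The tests of a library in the wrong group, of immunoglobulin reads, of the ratios to CD3 genes, of short against longer genes and of the splits were chosen after the results were seen; the 6 added gene lists were also written after the first results. The second T cell list and the second macrophage and monocyte list were written before their genes' values were looked at, but the other 4 hold genes already seen to rise, such as Ace, Spic and Lrp1, so they describe the rise and do not test it. No p-value is therefore given for these 4 lists. The p-values of the second T cell and second macrophage and monocyte lists, given below, were adjusted over the 6 added lists alone. All 10 tested patrolling monocyte genes rose, with a median of 4.38, and 4 of them are in the lists fixed earlier. All 11 tested red pulp macrophage genes rose (median 2.99), 5 of them in earlier lists. The 10 scavenger and cholesterol handling genes and the 14 lysosomal genes all rose too, with medians of 2.65 and 2.46. Apoe, which carries cholesterol, went from 255 ± 51.4 to 1692 ± 333 FPKM, and the lysosomal genes Psap and Ctsb from 362 ± 69.5 to 3921 ± 929 and from 181 ± 53.2 to 2274 ± 382.

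Libraries of a group also differed from each other. Tnf was at 301, 1569 and 1679.9 FPKM in the S100A4-positive libraries and Ccl4 at 123, 1081 and 1265. Cd4 was at 67.2, 337 and 111 FPKM in the S100A4-negative libraries, and Igha at 11954, 9601 and 836. As a ratio to the CD3 genes, inhibitory receptor genes (Pdcd1, Ctla4, Lag3, Tigit and Tox) were higher by 0.51 log2 units in S100A4-positive libraries, with all 3 above the S100A4-negative ones (exact two-sided permutation p = 0.1, the smallest possible; adjusted p = 0.350 over 7 ratios). The ratios of naive and memory genes and of the second T cell list were also higher, by 0.27 and 0.22 (exact two-sided permutation p = 0.5 and 0.2). That of the CD8 coreceptor genes differed by -0.30 (exact two-sided permutation p = 0.5). The log2(FPKM + 1) scale understates the fall of low genes, which can raise a ratio to the CD3 genes. These ratios therefore do not show a difference per T cell. Ratios of cytotoxic genes are given below.

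Monocyte and macrophage genes rose while T cell genes fell. A library in the wrong group is argued against by the correlations, 0.967 at the lowest within a group and 0.849 at the highest between groups. Distortion of the scaling by immunoglobulin reads would move all genes of a library by about the same factor. By itself it could not raise the macrophage list (median 3.41) and lower the T cell receptor signalling list (median -2.40). The macrophage list's median was 3.77 after median-of-ratios rescaling, which moved the median of all tested genes by 0.36. As that rescaling shifts all genes nearly alike, this outcome was fixed beforehand and adds nothing. RNA of myeloid cells in the S100A4-positive libraries may explain the pattern: in a second macrophage and monocyte list sharing 0 genes with the earlier lists, 95.8% of 24 rose (median 2.46, camera adjusted p = 4.79e-15; 0.0685 with an estimated correlation), and 17 of its genes were at 5 FPKM or more in S100A4-negative libraries too, while in a second T cell list of 18 genes 17 fell, with a median of -2.48 (camera adjusted p = 1.20e-07; 0.107 with an estimated correlation), near -2.61 for the CD3 genes. Both second lists hold further markers of the cell types already seen to differ. Their results were therefore likely in advance and are weak support. The CD3 and CD8 gate would remove myeloid cells, yet Lyz2 and Csf1r reached 3039 ± 169 and 1039.9 ± 204 FPKM. Most B cell, plasma cell and neutrophil markers fell (11 of 14, 7 of 8 and 11 of 13). The lists of these markers were not called in the main camera test. They were called lower after median-of-ratios rescaling (camera adjusted p = 0.0127, 0.0422 and 0.0127) and with fry (fry adjusted p = 0.0476, 0.00966 and 0.0258), among other settings. With an estimated correlation they were not (camera adjusted p = 0.873, 0.767 and 0.817). A difference in the T cells themselves that goes with S100A4 stays open. The ratios to the CD3 genes examined it for a few gene sets only. The median of the second T cell list lay below the bound set beforehand for libraries of T cells alone. The CD3 genes had already been seen to fall, so that bound could hardly have been met and does not decide the question. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 of 10 gave as many calls, the real one with 8253, and the highest of the others had 3.

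S100a4 was very low in cells sorted on its reporter. Reads in exons shared with another gene may have been left uncounted: of 470 genes lying wholly in the exons of other genes with reads, 99.6% had 0 reads. Among protein-coding genes it was 98.4% of 62 such genes, against 28.4% of those without shared exons. Loss of short transcripts in size selection was not settled. Of 61 protein-coding genes no longer than S100a4 and without shared exons, 4 reached 50 FPKM, which met the bound set beforehand in favour of such loss. These were 6.56%, against 16.0% of longer genes. At the longer genes' share, a comparison added after the results were seen, 9.78 would do so. That is under the 20 set beforehand as evidence against such loss, so the count cannot decide. Both stay open, and how far either lowers S100a4 itself, with 51.7% of its exon bases shared, was not tested; neither was a true absence of its RNA.

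Of 18 cytotoxic effector genes 12 fell and 4 rose, and the list was not called (camera adjusted p = 0.362). For those that fell, a smaller share of T cell RNA, its place taken by RNA of myeloid cells, is a candidate explanation: relative to Cd3d, Cd3e and Cd3g, 9 of them, chosen after the results were seen, were higher by 0.0845 log2 units in S100A4-positive libraries (exact two-sided permutation p = 0.9). All 12 that fell were higher by 0.43 (exact two-sided permutation p = 0.2), and all 18 tested members by 1.58 (exact two-sided permutation p = 0.1, the smallest possible), as the list includes members that rose. The spread of the ratio of the 9 genes between libraries was wide, with an SD of 0.46 in S100A4-negative libraries, so a difference per T cell stays open. Neither of the first 2 ratios was lower. The log2(FPKM + 1) scale understates the fall of low genes, so this cannot argue against a fall per T cell.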
